A study of Arabidopsis thaliana with 6 samples.

How the data were processed

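The data are RNA sequencing libraries from whole seedlings of Arabidopsis thaliana aged 14 days, 3 of wild type and 3 of the val1 val2 pkl mutant, grouped by the genotype that the sample labels state. Total RNA was extracted with a plant RNA column kit and libraries were made by standard Illumina methods, per the labels' protocols. TopHat, Cufflinks 2.1.1, Cuffdiff 2.1.1 and the genome build TAIR10 are named, per the submitters' processing notes. Strandedness, read length, read number and filters are not given in the sources used here.

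The authors' values are in a gene-level table of 31803 loci in the layout of Cuffdiff. It gives FPKM (fragments per kilobase of transcript, scaled to library size), deposited as 1 value for each of 2 genotypes and none for single libraries, so the spread between libraries and the depth per library are unknown. Low FPKM values times gene length, looked at once in a histogram, showed a lower edge and no clean steps of whole reads. A p-value and a q-value per locus were deposited by the authors for the comparison of both genotypes, with the smallest p at 5.00e-05, which 51.2% of tested loci share. The test statistic, a score deposited by the authors, has the opposite sign to the fold change in all 19823 tested loci above 0 in both genotypes and was not used. Status words in the deposited table mark 20678 loci as tested, 11123 as not tested, 1 as too deep to estimate and 1 as failed.

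The column of the mutant stands before that of wild type in the file, and the deposited log2 fold change equals mutant over wild type, within 0.01, in 20993 of the 20994 loci above 0 in both genotypes. In 2652 loci with 0 in a genotype the deposited log2 fold change holds spreadsheet error text. Fold changes were therefore recomputed from the FPKM values, and a locus at 0 in 1 genotype was given no fold and is described as listed at 0, since an exact 0 can be a failed estimate. In counts by fold and in list tests with a 2-fold minimum such loci were still kept. The summed FPKM was 912715 in wild type and 890451 in the mutant, and the median log2 fold change of 15751 tested loci at 1 FPKM or more in both genotypes was 0.07.

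Calls follow the test fixed in advance, the authors' q under 0.05 at loci marked as tested. For gene lists, families and promoters, loci that name exactly 1 gene were used, and where a gene had several the one with the highest summed FPKM, which left 18325 genes. The 1954 loci that name more than 1 gene, 6.14% of all, merge neighbours and were counted only in the totals over loci. Locus starts count from 0 in the file and were raised by 1 for print. Gene identifiers matched the TAIR10.1 reference annotation in 29005 of 29632 loci that name 1 gene, and 29004 of those overlapped the reference gene of that name, so its coordinates were used for promoters.

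The 21 gene lists, the product-name families (at least 10 tested members, 28 families left) the call rule and the rule for named genes were fixed before the data were examined. The rule names VAL1, VAL2 and PKL, then among called genes above 0 in both genotypes and at 10 FPKM or more in 1 of them the 8 largest folds in each direction, then the 4 called genes of highest FPKM listed at 0 in either genotype, then every member of a list with at most 6 tested members and otherwise the 4 called members with the largest fold. In that last step a fold against 0 was ranked as the largest, with ties ordered by FPKM, a reading chosen after the values were seen. For each list called rises and called falls were compared with all other tested genes by two-sided Fisher's exact tests, adjusted by Benjamini and Hochberg over 42 tests, and over 56 tests for families. A list's median change on the log2(FPKM + 1) scale was placed among 10000 random lists of the same size, matched on expression in 20 bins. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the authors' p-values of the list's tested members. Promoters were the 1000 bp before the annotated start, and the controls were all 179 other hexamers with the bases of CATGCA. Base composition had also been set down as an explanation of the RY result for the closing part and was dropped there after its result was seen, since the control hexamers in the report give that result.

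The list test was tested on simulated calls over 18325 genes, where 10 of 10 planted lists of 20 genes were recovered and 5 of 100 unplanted lists gave a p under 0.05. Most genes of a planted list were called, and recovery was judged by the unadjusted p and the percentile. Most real lists have fewer tested members, so the power of the adjusted test for them is not shown. Simulated calls were drawn independently for each gene. The rate of false passes for lists whose members move together is therefore not shown either. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a q under 0.01, a 2-fold minimum, minimum FPKM values of 1 and 5, centred folds, a recomputed adjustment, removal of overlapping loci, another list background, a pseudocount of 0.1, other promoter windows, a longer RY form and organelle shares without the 10 highest loci. Leaving out libraries, another normalization and splits of the samples need values per library and were not run.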

Results

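RNA was sequenced from whole Arabidopsis thaliana seedlings aged 14 days and grown in long days. The samples fall into 2 genotypes, 3 libraries of wild type and 3 libraries labelled val1 val2 pkl, a mutant in 3 genes. VAL1 and VAL2 encode B3-domain repressors that bind the RY element of seed gene promoters, and PKL (PICKLE) encodes a chromatin remodeller of the CHD3 type. The comparison asks which genes differ in expression between the mutant and wild type seedlings. Expression is given as the authors' value in FPKM for each genotype, combined over its 3 libraries, so no spread between libraries can be given and the depth of each library is unknown. A gene is said below to have risen or fallen where the q value in the authors' deposited table was under 0.05, and values are written from wild type to val1 val2 pkl. Whether the libraries of 1 genotype came from separately grown plants is not given in the sources used here, so the authors' p-values may measure only technical spread.

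Of the mutated genes, PKL (AT2G25170, chromosome 2, 10712606 to 10723987 in TAIR10) fell from 24.9 to 6.80 FPKM. The authors' values of VAL1 (AT2G30470, chromosome 2, 12980507 to 12985043) rose from 14.7 to 17.7 FPKM and those of VAL2 (AT4G32010, chromosome 4, 15479450 to 15485353) from 12.7 to 19.1 FPKM. The q values in the authors' deposited table were 9.76e-05 for PKL, 0.0174 for VAL1 and 9.76e-05 for VAL2. A value over a whole locus does not show whether its transcript is intact, so VAL1 and VAL2 do not check the genotype label, and the alleles are not given in the sources used here. VAL1 did not pass a stricter q of 0.01. Among the relatives of these genes PKR1 fell from 15.4 to 10.5 FPKM, VAL3 stood at 0.861 and 1.04 FPKM without a call, and PKR2 stood at 0.0122 and 39.8 FPKM, also without a call. Over the VAL and PKL family, 2 of 6 tested members rose and 2 fell, with 2 and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 1 in both directions).

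The mutant seedlings expressed genes of the seed at very high levels and had lost most of the expression of nuclear photosynthesis genes. Storage protein genes that were listed at 0 or under 0.4 FPKM in wild type were among the most abundant transcripts of the mutant. SESA3, a seed storage albumin, went from 0 to 23298 FPKM, and RBCS3B, a small subunit of Rubisco, from 5451 to 7.26 FPKM. Among all loci, 7188 rose and 7498 fell among 20678 tested, 71.0% of them. With loci listed at 0 in 1 genotype included, 3700 rose and 5141 fell at 2-fold or more, and 1043 and 2036 at 10-fold or more.

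**Figure D1:**
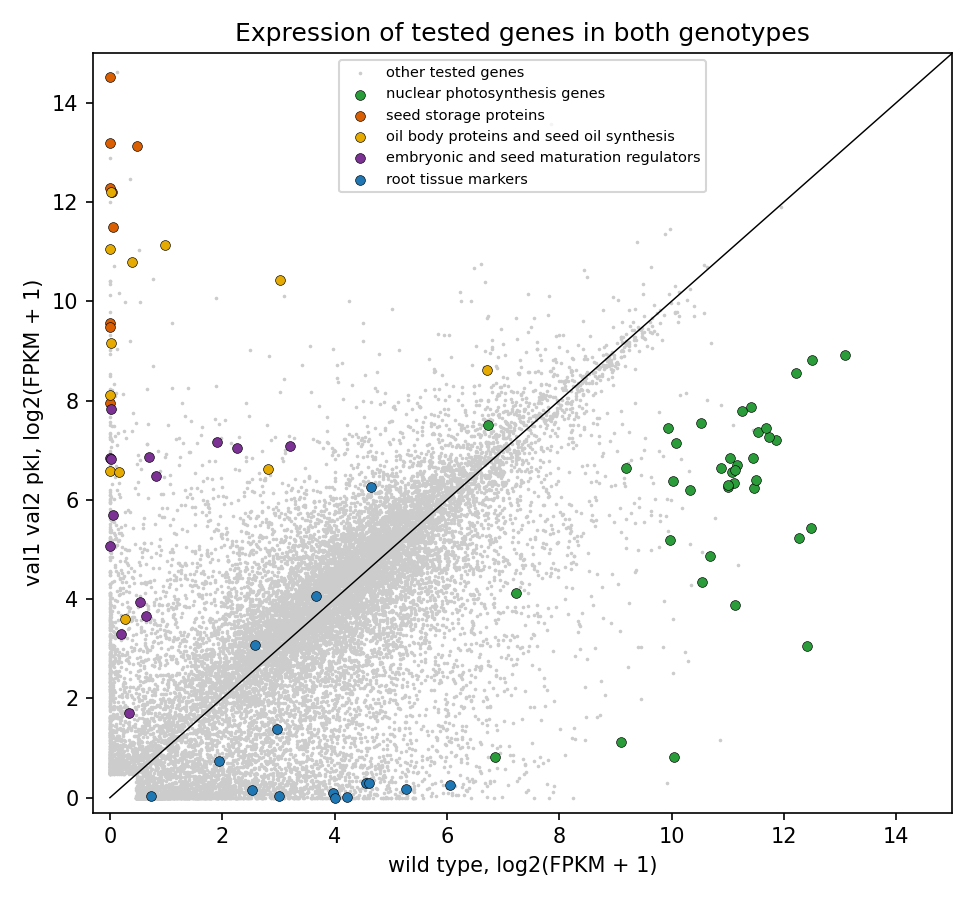
Expression of each tested gene in wild type (x axis) and in val1 val2 pkl (y axis), both as log2(FPKM + 1) of the authors' values. Points are genes, coloured for 5 gene lists, and the line marks equal values. Storage protein genes lie along the left edge, where wild type is near 0, and photosynthesis genes lie far below the line, with LHCB4.3 above it.

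AT1G47540, annotated as a knottin of the scorpion toxin type, had the largest fold rise among called genes above 0 in both genotypes, from 0.0851 to 25296 FPKM, the highest value in the mutant. Its locus in the authors' table (chromosome 1, 17454920 to 17465313) is much longer than the annotated gene, which ends at 17456186. The cupin gene PAP85 rose from 0.0521 to 1665 FPKM, SESA4 (chromosome 4, 13613596 to 13614283) from 0.390 to 8951 FPKM and AT4G30880, of the lipid transfer and 2S albumin superfamily, from 0.288 to 5606 FPKM. ABI3, a B3-domain activator of seed maturation, rose from 0.0174 to 112 FPKM. The cupin gene AT4G36700 rose from 0.203 to 1013 FPKM, AT2G34700, of the pollen Ole e 1 allergen and extensin family, from 0.432 to 2086 FPKM, and the extensin-like gene AT5G59170 from 0.0835 to 285 FPKM. Called genes listed at 0 in wild type were led by SESA3, SESA2 at 9376 FPKM, AT5G38160 of the same superfamily at 7602 FPKM and the cruciferin gene CRC at 4969 FPKM in the mutant. The calls of AT1G47540, AT4G30880 and ABI3 did not pass a stricter q of 0.01.

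The carbonic anhydrase gene CA2 had the largest fold fall by the same rule, from 966 to 0.228 FPKM, and its relative CA1 fell from 1867 to 1.25 FPKM. CYP81F4, a cytochrome P450 gene of indole glucosinolate synthesis, fell from 169 to 0.0857 FPKM, the B-box gene BBX14 from 239.9 to 0.175 FPKM and the light-harvesting gene LHCB2.3 from 1049 to 0.770 FPKM. AT5G19190, of unknown function, fell from 220.2 to 0.203 FPKM, the tyrosine aminotransferase gene TAT3 from 97.2 to 0.103 FPKM and the transporter gene AT2G26690 from 81.2 to 0.102 FPKM. Listed at 0 in the mutant and called were the glycine-rich protein genes GRP9 and AT2G05510, at 302 and 224 FPKM in wild type, AT4G22485 of the lipid transfer superfamily at 187 FPKM and the aldolase gene FBA5 at 114 FPKM. The calls of CYP81F4 and LHCB2.3 did not pass a stricter q of 0.01.

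Regulators of embryo identity and seed maturation rose together. Among 14 tested members, 12 rose, 12 adjusted over the list alone, and none fell (Fisher's exact test for rises, odds ratio 11.2, adjusted p = 0.00190). LEC1, which sets embryo identity, went from 0 to 114 FPKM and ABI4 from 0 to 32.6 FPKM. DOG1, a regulator of seed dormancy, rose from 0.627 to 115 FPKM, beside ABI3 above. FUS3, a B3-domain regulator named after its values were seen, stood at 0.0140 and 227 FPKM without a call, with a q of 0.225 in the authors' deposited table. The other tested member without a call, BZIP67, also named after its values were seen, stood at 0.0362 and 50.8 FPKM. Among genes at 1 FPKM or more in both genotypes, a filter that drops members near 0 in wild type, 3 members were left, all risen. With these the exact test did not pass (adjusted p = 0.274).

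Lists of storage proteins, oil genes and late embryogenesis abundant (LEA) proteins of seeds had much higher values in the mutant, although not all of their genes were called. Of the 9 storage protein genes 6 rose, 6 adjusted over the list alone, including SESA3, SESA2, CRC and SESA5, which went from 0 to 758 FPKM. The 3 storage genes without a call, named after their values were seen, were CRA1 at 0.0317 and 4713 FPKM, SESA1 at 0.0343 and 2898 FPKM and CRB at 0.00571 and 714 FPKM. Among oil body and seed oil genes 8 of 12 rose, 8 adjusted over the list alone. These included the oleosin gene OLEO3 from 0.972 to 2231 FPKM, FAE1, which elongates seed fatty acids, from 0 to 276 FPKM, the caleosin gene CLO2 from 0 to 95.1 FPKM and HSD5 from 0.112 to 93.8 FPKM. Among the LEA genes of the seed list 10 of 15 rose and 1 fell, with 10 and 1 adjusted over the list alone. LEA4-1 rose from 0.320 to 166 FPKM, XERO1 from 0.207 to 44.1 FPKM, ECP63 from 0.0575 to 39.2 FPKM and the LEA gene AT5G44310 from 0 to 22.7 FPKM. Over all 67 tested genes with a LEA product name 28 rose and 20 fell, with a median change of 0.51 on the log2(FPKM + 1) scale (Fisher's exact test for rises, adjusted p = 0.433). By Fisher's exact test of called rises none of the 3 lists passed, with adjusted p = 0.155 for storage proteins, 0.0729 for oil and 0.0546 for LEA proteins. Their median changes on the log2(FPKM + 1) scale, 12.16, 7.76 and 3.42, each lay at percentile 100 of 10000 random lists matched on expression. With a minimum of 2-fold, genes listed at 0 in wild type included, all of these exact tests passed, at adjusted p = 0.00738, 0.00233 and 4.715e-04. Without genes listed at 0 none passed, with adjusted p = 1 for storage proteins, where 1 of 4 members left rose (odds ratio 0.624), 0.171 for oil and 0.0935 for LEA proteins by the same exact test. That filter drops storage genes called from 0 in wild type and leaves SESA4 with the 3 uncalled ones above. None of them fell, so the low odds ratio follows from the filter.

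**Figure D2:**
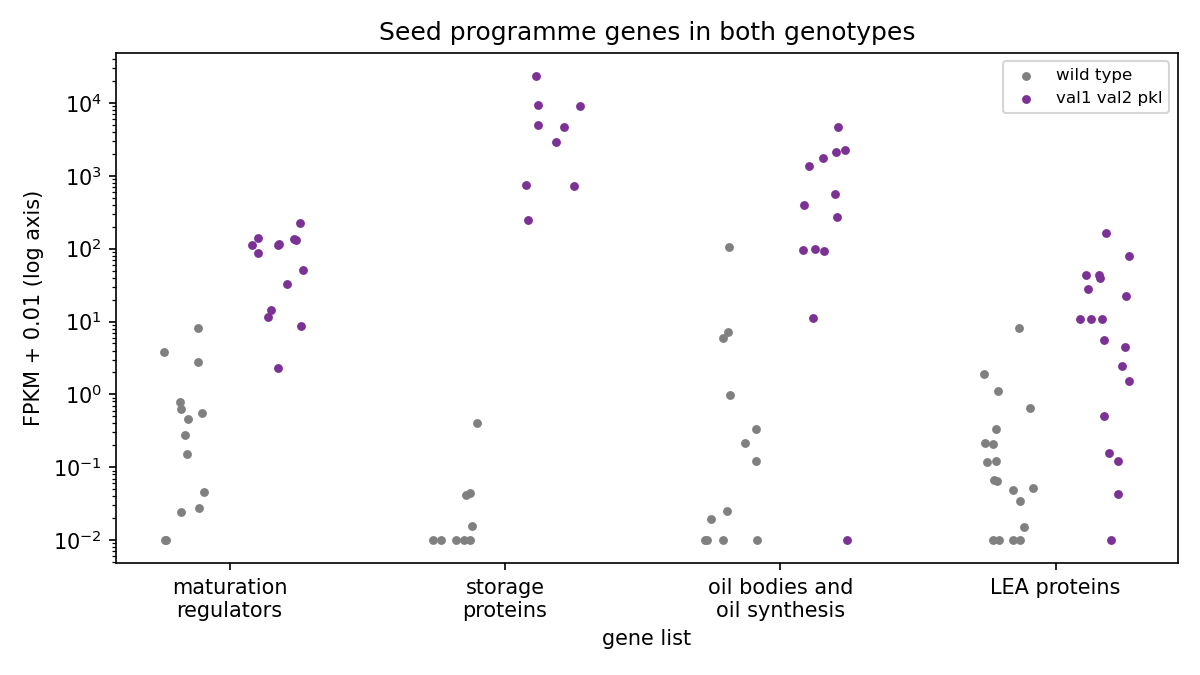
Expression of the members of 4 seed gene lists in wild type (grey) and val1 val2 pkl (purple), as FPKM + 0.01 of the authors' values on a log axis, 1 point per gene, members without a test included. Storage protein genes stand between 247 and 23298 FPKM in the mutant, and LEA genes between 0 and 166 FPKM.

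Genes of meristems and of the root and embryo stem cells were higher in the mutant. All 8 tested WOX and PLETHORA genes rose, 8 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00230). WOX9 rose from 0.151 to 39.4 FPKM, AIL5 from 1.93 to 139.6 FPKM, WOX5, a marker of the root stem cell niche, from 1.03 to 56.3 FPKM and PLT2 from 1.01 to 16.7 FPKM. Of 9 shoot meristem and boundary genes 7 rose, 7 adjusted over the list alone, and the test of the list gave an adjusted p = 0.0511 (Fisher's exact test). WUS, which maintains shoot stem cells, went from 0 to 6.13 FPKM, CUC1, an organ boundary gene, from 0.5003 to 42.3 FPKM, KNAT6 from 5.50 to 53.8 FPKM and KNAT2 from 0.966 to 6.36 FPKM. Of 9 tested mitotic cell cycle genes, 6 rose and 1 fell, with 6 and 1 adjusted over the list alone (Fisher's exact test, adjusted p = 0.155), and the largest rises were in KNOLLE, from 25.8 to 62.1 FPKM, CDKB1-2, from 4.71 to 11.3 FPKM, CDKB2-1, from 16.9 to 35.1 FPKM, and CDKB2-2, from 12.5 to 21.5 FPKM.

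Polycomb genes, whose products repress genes by histone marks, mostly rose. Of 13 tested, 9 rose and 2 fell, with 9 and 2 adjusted over the list alone, and the list did not pass (Fisher's exact test, odds ratio 4.204, adjusted p = 0.0561). BMI1A rose from 8.39 to 63.7 FPKM, BMI1B from 7.19 to 27.9 FPKM and RING1B from 6.78 to 19.0 FPKM, all of PRC1, the complex that ubiquitinates histone H2A. MEA, an endosperm gene of PRC2, fell from 0.419 to 0.0402 FPKM.

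Nuclear genes of photosynthesis fell almost throughout. Of 38 tested, 37 fell and 1 rose, with 37 and 1 adjusted over the list alone (Fisher's exact test for falls, odds ratio 63.5, adjusted p = 9.50e-14). The median change was -4.49 on the log2(FPKM + 1) scale, percentile 0 of 10000 matched random lists. Beside RBCS3B and LHCB2.3, LHCB1.4 fell from 549 to 1.16 FPKM and LHCB2.2 from 2250 to 13.7 FPKM. LHCB4.3, the member that rose and named for that reason, went from 104.8 to 181 FPKM. Loci of this list that name 1 gene held 10.3% of the summed FPKM of wild type, where RBCS1A is listed at 0 by a failed estimate, and 0.607% of that of the mutant, or 0.510% without RBCS1A, whereas storage protein genes held 5.05e-05% and 6.28%. Near-identical copies among the LHCB1, LHCB2 and RBCS genes can share reads, so their single values are uncertain.

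Root marker genes fell more often than they rose. Of 15 tested, 10 fell and 3 rose, with 11 and 3 adjusted over the list alone (Fisher's exact test for falls, odds ratio 3.42, adjusted p = 0.0729), and the median change of -2.97 lay at percentile 0 of the matched random lists. The iron transporter gene IRT1 went from 15.02 FPKM to 0, the root hair gene COBL9 fell from 7.01 to 0.0210 FPKM, the phosphate exporter gene PHO1 from 65.3 to 0.200 FPKM and CASP1, of the endodermal barrier, from 37.8 to 0.132 FPKM. Transcription factor genes of the list, named after their values were seen, went both ways. SCR (24.2 to 75.1 FPKM), SHR (11.7 to 15.7 FPKM) and WER (4.99 to 7.47 FPKM) rose, and GL2 (6.83 to 1.60 FPKM), RHD6 (2.86 to 0.664 FPKM) and MYB36 (4.78 to 0.113 FPKM) fell. With a minimum of 2-fold the exact test for falls passed, at adjusted p = 0.00523. Among the 4 members at 1 FPKM or more in both genotypes 1 fell and 3 rose (odds ratio 0.638, adjusted p = 1, same exact test). That filter drops members because they fell under 1 FPKM in the mutant, such as COBL9, PHO1 and CASP1, so it is no test of the falls.

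Defence genes fell. Of 16 tested, 13 fell, 13 adjusted over the list alone, and none rose (Fisher's exact test for falls, odds ratio 7.41, adjusted p = 0.00317). The defensin gene PDF1.2A fell from 59.9 to 0.201 FPKM, ALD1, of systemic resistance, from 4.52 to 0.0490 FPKM, the jasmonate synthesis gene LOX2 from 73.9 to 0.988 FPKM and PR1, a salicylic acid marker, from 528 to 18.9 FPKM. The list did not pass when calls needed a q under 0.01 (exact test, adjusted p = 0.0843), and the call of ALD1 did not either. Leaf senescence genes also fell in 5 of 6 tested members and rose in 1, with 5 and 1 adjusted over the list alone (Fisher's exact test for falls, adjusted p = 0.0729). SEN1 fell from 48.4 to 0.437 FPKM, ORE1 from 28.3 to 0.705 FPKM, NAP from 43.6 to 7.66 FPKM, SAG13 from 46.1 to 12.9 FPKM and NYE1, not past a q of 0.01, from 21.2 to 17.2 FPKM, while WRKY6 rose from 16.6 to 55.1 FPKM.

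Flowering genes went both ways. Of 17 tested MADS-box genes 7 rose and 6 fell, with 7 and 6 adjusted over the list alone (Fisher's exact test, adjusted p = 0.777 for rises and 1 for falls). FLC, a repressor of flowering, rose from 1.70 to 190.0 FPKM, whereas SVP, another repressor, fell from 40.3 to 0.116 FPKM, SOC1, which promotes flowering, went from 10.9 FPKM to 0, and the floral organ gene AG from 0.588 FPKM to 0. Of 4 tested genes outside the MADS-box family, 1 rose and 2 fell, with 1 and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 1 for rises and 0.777 for falls). The florigen gene FT went from 2.92 FPKM to 0 and TFL1 from 3.75 FPKM to 0. TSF, not past a q of 0.01, rose from 0.0831 to 0.540 FPKM, and CO stood at 1.04 and 3.70 FPKM without a call. The falls of SOC1, AG, FT and TFL1 are calls of genes listed at 0 in the mutant. Of 855 tested loci listed at 0 in 1 genotype, 687 have the smallest p, at a median of 1.88 FPKM in the other genotype. Such calls at a few FPKM or less are therefore uncertain, here and in the other lists.

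Hormone genes moved in both directions. Among gibberellin genes 9 of 19 tested rose and 6 fell, with 9 and 6 adjusted over the list alone (Fisher's exact test for rises, adjusted p = 0.502). GA20OX3, which makes gibberellin precursors, rose from 0.175 to 279.8 FPKM, the receptor genes GID1C and GID1B fell from 12.6 to 0.240 FPKM and from 13.7 to 0.730 FPKM, and GA2OX1 went from 0.531 FPKM to 0. Among auxin genes 9 of 17 rose and 5 fell, with 9 and 5 adjusted over the list alone (adjusted p = 0.2498 by the same exact test). The auxin synthesis genes YUC4 and YUC1 rose from 0.490 to 27.7 FPKM and from 0.187 to 3.53 FPKM, YUC2 went from 2.05 FPKM to 0, and IAA30 rose from 2.33 to 86.1 FPKM. Among abscisic acid genes 7 of 13 rose and 5 fell, with 7 and 5 adjusted over the list alone (adjusted p = 0.265 by the same exact test). The synthesis gene NCED6 was called at 0 and 0.666 FPKM, NCED9 rose from 0.0682 to 5.999 FPKM and NCED5 from 0.121 to 2.48 FPKM. The drought response gene RD22 fell from 138 to 8.06 FPKM. The calls of NCED6, GA2OX1 and YUC2 rest on a listed 0 and a low value in the other genotype, so they are uncertain. With a minimum of 2-fold the lists passed for rises by the exact test, at adjusted p = 0.0124 for gibberellin, 0.0186 for auxin and 0.0135 for abscisic acid.

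Flavonoid, clock and pollen genes completed the lists. Of 13 flavonoid genes 3 rose and 6 fell, with 3 and 6 adjusted over the list alone (Fisher's exact test for falls, adjusted p = 0.770). PAP1, an activator of anthocyanin synthesis, went from 1.86 FPKM to 0, UF3GT, not past a q of 0.01, fell from 1.01 to 0.0405 FPKM and TTG2 from 2.13 to 0.548 FPKM, while the flavonoid hydroxylase gene at AT5G07990 rose from 13.6 to 142.5 FPKM. Of 8 clock genes 5 rose and 3 fell, with 5 and 3 adjusted over the list alone (Fisher's exact test for rises, adjusted p = 0.2502). RVE1 and CCA1 fell from 45.8 to 4.97 FPKM and from 130.4 to 19.2 FPKM, and PRR5 and LUX rose from 0.949 to 3.54 FPKM and from 9.07 to 23.2 FPKM. Of the other members, named after their values were seen, PRR9 rose from 5.38 to 8.25 FPKM, TOC1 from 10.9 to 19.9 FPKM and ELF3 from 8.98 to 14.6 FPKM, and ELF4, not past a q of 0.01, fell from 14.4 to 10.98 FPKM. The 2 tested pollen and tapetum genes both rose, 2 adjusted over the list alone (Fisher's exact test, adjusted p = 0.243), VEX1 from 1.25 to 147.7 FPKM and LTP12 from 0 to 2.56 FPKM.

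**Figure D3:**
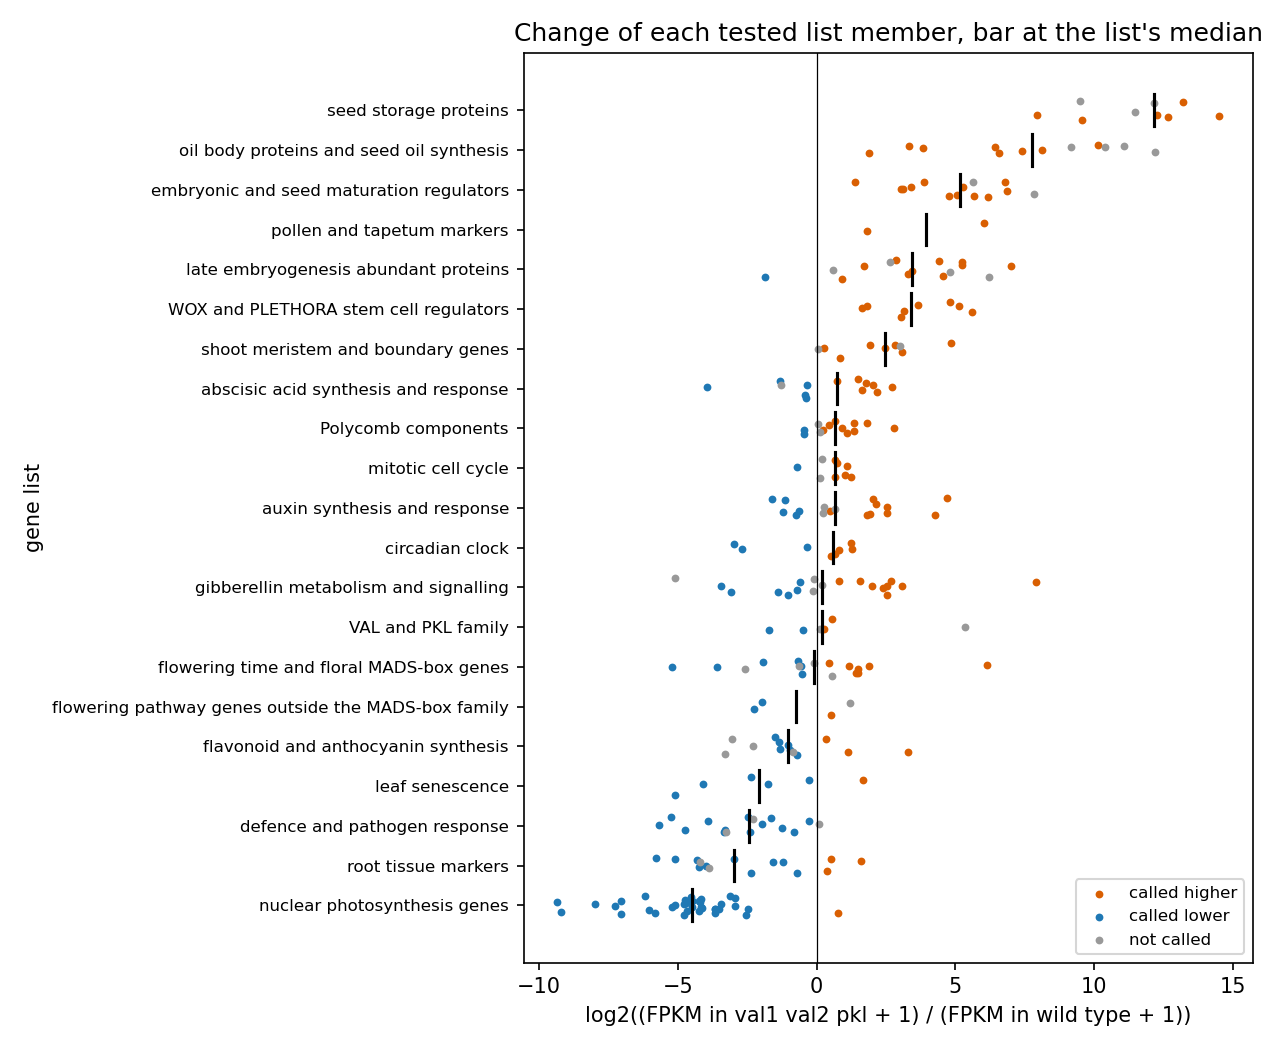
Change of each tested member of the 21 gene lists (y axis) as log2 of the FPKM + 1 of val1 val2 pkl over that of wild type (x axis), with 1 point per gene coloured by the authors' call and a bar at each list's median. Medians run from -4.49 for photosynthesis genes to 12.16 for storage proteins.

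Gene families taken from the annotated product names moved in the same comparison. Of the 18325 genes tested in these counts 34.9% rose and 36.9% fell. Genes with histone in their product name rose in 55.7% of 79 members (Fisher's exact test, odds ratio 2.36, adjusted p = 0.00221). They fell in 19.0% (adjusted p = 0.00604), although at 2-fold or more their rises did not pass (adjusted p = 0.425), by the same exact test. This set is matched by text and holds LEC1, so it is not made of histones alone. Resistance genes of the NBS-LRR type fell in 60.3% of 68 members (odds ratio 2.60, adjusted p = 0.00169 by the same exact test). Cytochrome P450 genes fell in 52.6% of 156 members (exact test, adjusted p = 0.00148), peroxidase genes in 53.8% of 80 (adjusted p = 0.0167) and genes of cysteine-rich proteins in 52.9% of 68 (adjusted p = 0.0440). Fewer ribosomal protein genes rose than elsewhere, 20.5% of 263 (exact test, adjusted p = 1.18e-05). Their falls, 29.7%, were not more frequent either (adjusted p = 0.0672 by the same exact test). Of the 263 genes 131 had no call, against 5164 of all 18325, so this is no shift downward. Fewer SAUR genes rose too, 16.1% of 62 (exact test, adjusted p = 0.0102), while 46.8% fell. Pentatricopeptide genes, whose products act in organelle RNA processing, fell in 17.2% of 174 (exact test, adjusted p = 7.59e-07) and F-box genes in 26.3% of 167 (adjusted p = 0.0290). Rises in these families, 36.2% and 36.5%, were near the share of all genes, and 81 and 62 members had no call. No other of the 28 families tested passed in either direction, and at 2-fold or more the smaller share of rises among SAUR genes did not pass (exact test, adjusted p = 0.727).

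RY elements, which VAL proteins bind, were more frequent before genes that rose. Binding was not measured, and ABI3, also a B3-domain protein, rose in the mutant, so the element cannot show which genes VAL binds. At least 1 CATGCA on either strand stood in the 1000 bp before the annotated start of 35.6% of 6375 risen genes and of 31.0% of 5146 genes without a call (odds ratio 1.23, 95% confidence interval 1.14 to 1.33, two-sided Fisher's exact test, adjusted p = 4.92e-07). Before the 6745 fallen genes the share was 33.4% (odds ratio 1.12, interval 1.03 to 1.21, exact test, adjusted p = 0.00530). For genes that rose by 2-fold or more the share was 41.6% and the odds ratio 1.59. None of the 179 other hexamers with the same bases reached the odds ratio of the RY element for risen genes, where their highest was 1.17, and 3 of them reached it for fallen genes. Genes are not independent replicates, and the longer form CATGCATG gave no call for fallen genes (odds ratio 1.14, p = 0.227, Fisher's exact test).

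**Figure D4:**
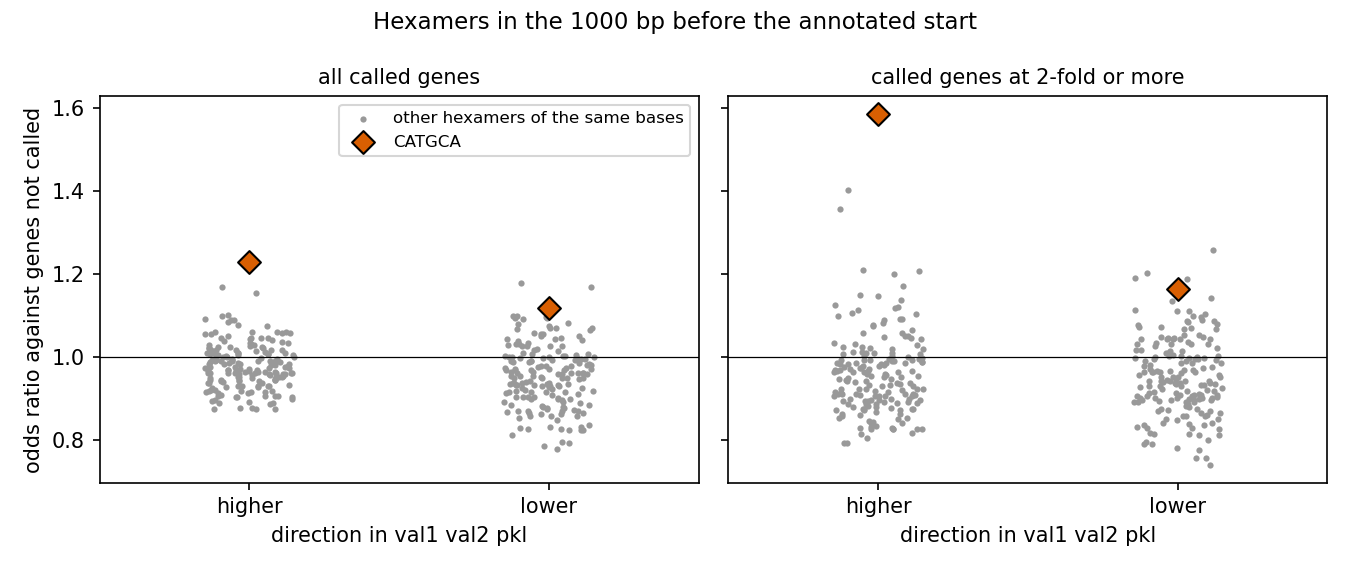
Odds ratios (y axis) of carrying a hexamer in the 1000 bp before the annotated start, for genes called higher and lower in val1 val2 pkl against genes not called, for all called genes (left) and those at 2-fold or more (right). Diamonds mark CATGCA and grey points the 179 other hexamers of the same bases. The diamond for higher genes stands at 1.23 on the left and 1.59 on the right, above all grey points.

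Loci of the organelle genomes held a small part of the summed FPKM in both genotypes. Chloroplast loci held 0.0685% of the summed FPKM in wild type and 0.0218% in val1 val2 pkl, and mitochondrial loci 0.00513% and 0.0110%. These are sums of the authors' values, with no test. Such shares depend on how RNA was selected for the libraries, so they do not give levels in the plant.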

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

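All tests of explanations in this part were chosen after the results they bear on had been seen. RBCS1A, a small subunit gene of Rubisco, was marked as too deep to estimate and is listed at 0 in wild type and at 866.7 FPKM in val1 val2 pkl, a signal in a locus outside the tested ones. Its 0 in wild type is a failed estimate and gives no direction. Loci without a gene name, which no gene list covers, were also called, and 100 of 201 tested rose and 29 fell. The highest of those that rose lies on chromosome 4 from 16248572 to 16249301 and went from 0 to 121 FPKM, and 35 of the unnamed loci called were listed at 0 in wild type.

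Large differences stood without a call, as for SESA1, CRA1, FUS3 and PKR2. Among loci at 10 FPKM or more in the mutant, the uncalled share was 14.4% where wild type was listed at 0, 73.2% where it was above 0 and under 0.1 FPKM, 9.66% from 0.1 to under 1 FPKM and 1.56% from 1 to under 5 FPKM, and in the opposite direction the shares were 23.8%, 63.8%, 5.23% and 1.71%. In both directions the uncalled share was thus highest just above 0. Whether the authors' test itself loses calls there stays open. The smaller gap between the loci just above 0 and those at 0, 39.9 percentage points, leans on loci listed at 0. With loci under 10 FPKM included, 687 of 855 tested loci listed at 0 share the smallest p in the authors' deposited table. The shares from 0.1 FPKM on were set beside that gap only after they had been seen. Whether mutant replicates differ in the seed programme stays open too, since no values per library are given and their spread need not act alike at every wild type level. Among seed-list genes at 10 FPKM or more in the mutant, 8 of 10 were uncalled where wild type was above 0 and under 0.1 FPKM, 2 of 22 where it was at 0.1 FPKM or more (Fisher's exact test, p = 1.65e-04) and, in a first form of the test that was replaced after it was seen, 1 of 11 at exactly 0 (p = 0.00191).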

How the results depend on the processing

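No paired analysis was possible because the deposited values are combined over the libraries of each genotype. For the same reason leaving out a library, another normalization and other splits of the samples were not run, and depth limits cannot be stated. The alternatives with merged loci, with 1 FPKM in both genotypes, without genes at 0 and with calls by 20-fold at 10 FPKM were chosen after seeing the data. Of the results that answer a comparison 191 settings kept their direction and side of the threshold or stayed within 1.5 times, 31 passed newly, 5 no longer passed, 7 turned the direction of the odds ratio without passing and 1 count moved, and the cause was not tested unless stated. Risen loci were 7188 and ranged from 3700, at 2-fold, to 7283, and fallen loci were 7498 and ranged from 5141 to 7590.

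At 2-fold or more lists passed newly (adjusted p) for rises of storage proteins 0.00738, oil 0.00233, LEA 4.715e-04, shoot meristem 0.00738, gibberellin 0.0124, auxin 0.0186 and abscisic acid 0.0135, and for falls of root markers 0.00523. Families did so for rises of LEA 5.36e-04, MADS 0.0398, invertase inhibitor 5.26e-06 and defensin 0.0249, for falls of WRKY 0.00618, MYB 0.00374, lipid transfer 0.0164, xyloglucan endotransglucosylase 0.0164 and 2OG-dependent oxygenase 0.0452, and for fewer falls of heat shock 0.00155. Rises of genes with a histone product name 0.425 and fewer rises of SAUR 0.727 were lost. With a background of 1 FPKM in 1 genotype Polycomb 0.0445, LEA 0.0399, shoot meristem 0.0225 and the invertase inhibitor family 0.0431 passed. With merged loci Polycomb 0.0256, oil 0.0355 and shoot meristem 0.0369 passed. With calls also by 20-fold at 10 FPKM rises of Polycomb 0.0475, storage proteins 7.26e-04, oil 4.00e-05, LEA 0.00280 and shoot meristem 0.0385 and falls of root markers 0.00450 passed. At a q under 0.01 falls of defence genes were lost, 0.0843. With 1 FPKM in both genotypes, which leaves fewer genes, rises of maturation regulators were lost, 0.274 with 3 of 3 members risen, and storage proteins had no member left. The RY odds ratio for fallen genes was 1.14 with CATGCATG, past the threshold no longer. The odds ratio turned for storage proteins without genes at 0 (adjusted p = 1), for root markers with 1 FPKM in both genotypes (1), for flowering genes outside the MADS-box family in both of these settings (0.752 and 1), for the VAL and PKL family with 1 FPKM in both genotypes (0.934) and with calls by 20-fold (0.627), and for the auxin-responsive family at 2-fold (0.313), all by Fisher's exact test. For storage proteins, root markers and these flowering genes the filter drops called genes at or near 0 in 1 genotype. The change itself thus decided which genes were left, so these turns are no evidence on direction. Of the genes that the rule names 10 calls were lost at a q under 0.01, VAL1, AT1G47540, AT4G30880, ABI3, CYP81F4, LHCB2.3, TSF, ALD1, UF3GT and NYE1, and 6 list medians moved by 1 or more with a pseudocount of 0.1, each keeping its sign.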

Other observations

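All tests in this part were chosen after the results they bear on had been seen, as were the genes named here. Some of the highest values of the mutant were in genes outside the seed lists. The lipid transfer protein gene LTP2 stood at 231 FPKM in wild type and 12190 FPKM in the mutant, the extensin gene EXT3 at 1004 and 2805 FPKM and the peroxidase gene PRXR1 at 940.0 and 2628 FPKM. The metallothionein gene MT2A stood at 671 and 2343 FPKM, while its relative MT2B had similar values, 3944 and 3797 FPKM. DFR and LDOX, of anthocyanin synthesis, stood at 7.62 and 0.0340 FPKM and at 9.53 and 0.0747 FPKM without a call. GA3OX1, which makes active gibberellin, stood at 33.9 and 0.0249 FPKM, also without a call.

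Storage protein genes were high in the mutant while the LEA genes EM1, EM6 and ECP31, which are abundant in dry seeds, stood at 0.112, 5.51 and 0 FPKM, EM1 and ECP31 without a test. Other LEA genes stood higher, LEA4-1 at 166 FPKM and LEA18, without a call, at 80.5 FPKM. Dry seeds or seed remains in the mutant samples would bring EM1, EM6 and ECP31 transcripts along. Their median, which is the value of EM1, was 0.00239% of the storage protein median of 4713 FPKM. Over the 15 tested members of the LEA list the mutant median was higher, at 10.9 FPKM. EM1, EM6 and ECP31 were thus low beside the storage genes. That is part of the pattern that prompted the test, and no values of dry seeds were set beside it. The values therefore cannot decide on dry seeds, and no other stage of seed was tested.

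Photosynthesis genes were low in the mutant. A smaller share of green tissue alone would lower them by about 1 factor if the other tissue expressed none of them. The range of their log2 fold changes from the 10th to the 90th percentile was 4.33, from -7.28 to -2.96, with a median of -4.50. Expression in other tissue is unknown, and the largest falls include LHCB and RBCS copies of uncertain value. The range therefore cannot decide on green tissue. Seed transcripts that take a larger part of the mutant libraries would lower all other genes alike, and the 7.88% of summed FPKM in the storage, oil and LEA lists gives a log2 change of -0.12. That change is too small to account for the pattern. Less green tissue, alone or with lower expression within it, could not be tested in pooled values. An effect of the genotype itself stays open and was not tested apart from these.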
